A study of Danio rerio with 26 samples.

How the data were processed

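Transcript abundance was measured by RNA sequencing in the brain and the liver of adult zebrafish (Danio rerio, AB strain with short fins). Per the labels' protocols, males and females were kept apart, at 28 °C with 14 h of light and 10 h of darkness. The exposed fish spent 9 weeks in water with 0.5% ethanol that was renewed daily, and control fish were moved between tanks in the same way without ethanol. The labels describe 30 fish for each tank of control and alcohol-exposed males and females. For the withdrawal groups, which stopped the exposure, the duration without ethanol and the number of fish are not given in the sources used here. Tissue was pooled within groups before sequencing, so each library is a pool and nothing states that replicate libraries came from separate fish. All p-values below therefore measure only the spread between these libraries, which may be technical.

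Libraries were non-stranded and were sequenced on a HiSeq 2000, per the labels' protocols. Per the submitters' processing notes and the series design, reads were checked with FastQC 0.11.7, aligned with STAR 2.5.2 to the danRer10 build, and quantified per transcript with RSEM 1.3.1, and the authors tested differences with EBSeq. The authors deposited TPM (abundance relative to all transcripts of a library, summing to a fixed total) for 57918 Ensembl transcripts, as 1 table of 14 brain libraries and 1 of 12 liver libraries. TPM carries no read number, so the depth per library is unknown and no interval or detection floor that needs it is given. A transcript at exactly 0 TPM can be a failed allocation of reads between similar transcripts, so such values are described as listed at 0. In the brain 137 of the tested transcripts had the same values as another transcript in every library, and in the liver 61 did.

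The tables list transcripts by Ensembl transcript identifier. The reference tables used here list genes, and no map from transcript to gene was used, so no gene name, genomic position or annotation is given. The gene lists fixed in advance (ethanol metabolism, brain and liver pathways, markers of other cell types) and their set tests could not be run for that reason. Results are therefore given for transcripts, for classes of abundance and for groups of transcripts defined by their response.

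Computations were done in R 4.3.3 with limma 3.58.1 and in Python 3.11.15 with matplotlib 3.10.9 for the plots. Transcripts with at least 1 TPM in at least 2 libraries of a tissue were tested, which left 36682 in the brain and 21158 in the liver. TPM was rescaled between libraries by the median of ratios to the geometric mean, over the 27390 brain and 14468 liver transcripts above 0 in every library of the tissue. This rescaling assumes that the typical transcript did not change between groups. Values were taken as log2(TPM + 1), and every fold change below is on that scale, which understates changes of transcripts of low abundance. A limma model with a moderated variance trend was fitted to each tissue, with a mean for each of the 6 groups of sex and exposure, and comparisons were contrasts of those means. The average over sexes weighs males and females equally. A transcript was called at a Benjamini-Hochberg adjusted p below 0.05. Shares of TPM, abundance classes and median gains in TPM use TPM as the authors deposited it. Levels of single transcripts, including those named, switching or picked by their level, are given in TPM after the rescaling above. In the brain the rescaling divided TPM by 2.04 to 2.18 in alcohol-exposed libraries and by 0.60 to 0.95 in the others.

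On simulated data with known changes for the comparison of alcohol with control over both sexes, the procedure recovered 41.8%, 91.0% and 98.5% of changes of 0.5, 1 and 2 log2 units among 36682 brain transcripts, with 7 false calls (4.35% of calls). Among 21158 liver transcripts it recovered 8.96%, 76.1% and 95.5% of the same sizes, with 5 false calls (4% of calls). In each tissue only 66 or 67 transcripts of each size were changed. All of them had a mean log2(TPM + 1) above that of 5 TPM, so recovery at lower abundance was not assessed. The values were simulated after the rescaling, with independent normal noise. Errors of the rescaling, and false calls where a large part of the transcripts changes, were therefore not assessed.

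Transcripts called between alcohol and control were sorted by their state after withdrawal. They were still changed if called in the same direction against control, reversed if called in the opposite direction, and returned if not called against control and called back against alcohol. The rest were unresolved. The retained share is the covariance across transcripts of the withdrawal effect with the alcohol effect, divided by that of the alcohol effect with itself, using sets of control and alcohol libraries that do not overlap. A value of 1 means that the withdrawal difference matched the alcohol difference on average, and 0 that none of it was left. Its SD is taken over values with single withdrawal replicates. Transcripts named by identifier were those with the largest log2 change among called transcripts with at least 5 TPM on average in either group and the same sign in both sexes, 2 in each direction. The rule written in advance asked for 10 gene symbols in each direction, which these tables do not give.

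The groups, the model, the threshold and the alternatives to be tried were fixed before the data were examined. These alternatives were TPM without rescaling, a pseudocount of 0.1, no filter, the replicate number as a block, a fit of the compared groups alone, and leaving out each library in turn. Averaging of nearly identical library pairs and quantile normalisation were added after the data were seen. Replicate pairs were compared before averaging. The median absolute log2 difference between replicates, over transcripts of 10 to 100 TPM, was 0.0754 in female alcohol-exposed brain, 0.0833 in female alcohol-exposed liver, 0.0945 in female withdrawal liver and 0.0992 in male withdrawal brain, and between 0.153 and 0.318 in the other groups. Without counts these differences could not be set against sampling noise, so the pairs were kept as separate libraries.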

Results

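Transcript levels were compared between control, alcohol-exposed and withdrawal zebrafish of both sexes, in brain and in liver. The brain set held 14 libraries: 2 of control males, 3 of control females, 2 each of alcohol-exposed males and females, 3 of withdrawal males and 2 of withdrawal females. The liver set held 12 libraries, 2 in each of the 6 groups. The title of the series asks whether transcript levels recover after withdrawal and whether recovery depends on the tissue. Every library sums to the same TPM total by construction, so the depth behind each library is unknown.

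In the brain, exposure to alcohol separated the libraries more than sex did. The first principal component carried 34.9% of the variance and placed the 4 alcohol-exposed brain libraries between −118 and −109.2, while all other brain libraries lay at −2.45 or above. The component that followed carried 26.8% and placed control females and withdrawal males at −34.4 or below, with control males and withdrawal females at 52.3 or above. In the liver, the first component (37.6%) set the control males, at 150 and 157.6, apart from all other livers, which lay at 18.8 or below. The next liver component (25.2%) placed every female library at −23.5 or below and every male library at 3.13 or above.

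**Figure D1:**
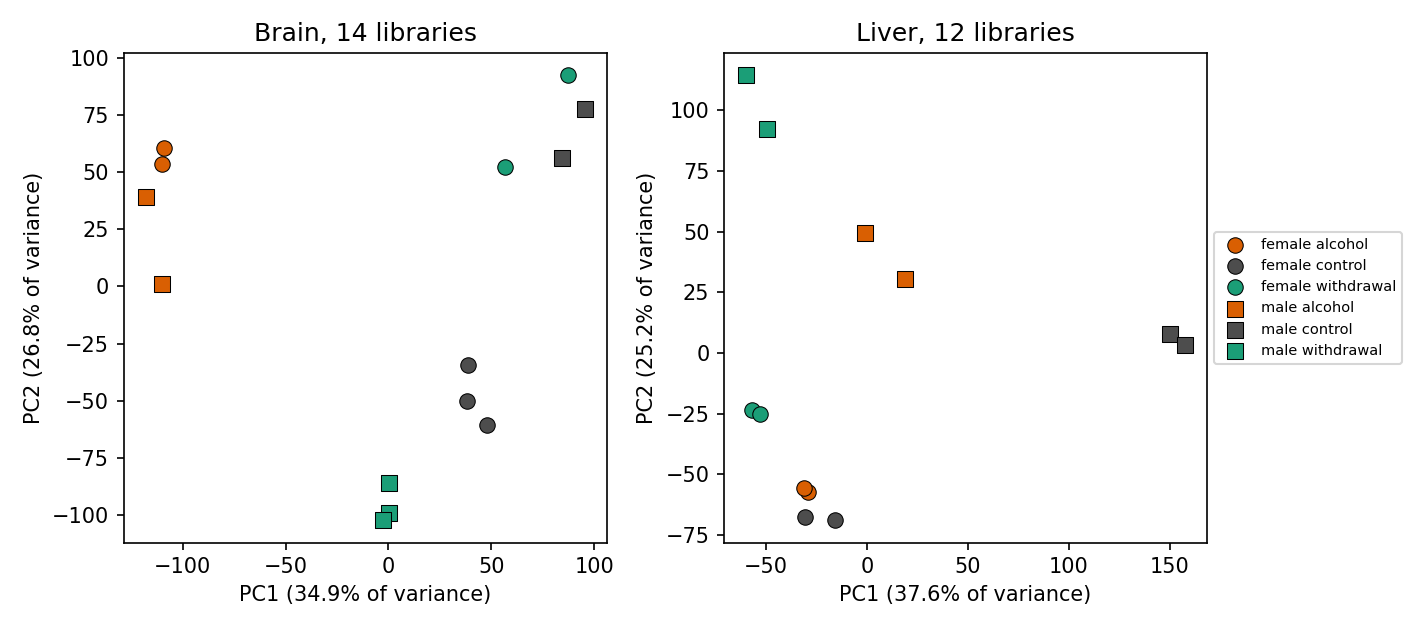
Principal components of log2(TPM + 1) after rescaling, for the 14 brain libraries (PC1 34.9% and PC2 26.8% of variance) and the 12 liver libraries (37.6% and 25.2%); each point is 1 library, with circles for females, squares for males and colour for exposure. Alcohol-exposed brains lie at PC1 values from −118 to −109.2 and control male livers at 150 and 157.6.

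After 9 weeks of exposure, alcohol and control brains differed according to transcript abundance. Abundant transcripts were lower: of the 676 transcripts with 100 to 300 TPM on average over the brain libraries, 651 fell, with a median log2 change of −2.32 for the class. In the 300 to 1000 TPM class 255 of 258 fell (median −2.32), and above 1000 TPM 75 of 81 fell (median −2.07). Transcripts of low abundance moved the other way, with 4076 of 11429 rising and 929 falling at 1 to 5 TPM (median 0.31), and 4964 of 11374 rising and 2073 falling at 5 to 20 TPM (median 0.24). The 1000 most abundant transcripts of a library held 43.5% ± 3.56 (SD, n = 4) of TPM in alcohol-exposed brains and 65.7% ± 4.19 (SD, n = 5) in control brains.

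The labels give no batch, and all 4 exposed brain libraries belong to the exposed groups alone, so exposure and library preparation cannot be told apart here. The difference in share exceeded the spread between libraries (−22.1 percentage points, exact two-sided permutation p = 0.00794, the smallest that 126 splits can give, and 0.0238 after Benjamini-Hochberg adjustment over 6 comparisons). In TPM without rescaling the class medians were −0.84, −0.82 and −0.56 for the 3 classes above 100 TPM, so their fall held, whereas the class of 20 to 100 TPM turned from −0.88 to 0.56. Quantile normalisation, which gives all libraries the same distribution, left class medians between −0.03 and 0.22, and turned the sign for 20 to 100 TPM (0.06) and for above 1000 TPM (0.00574).

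**Figure D2:**
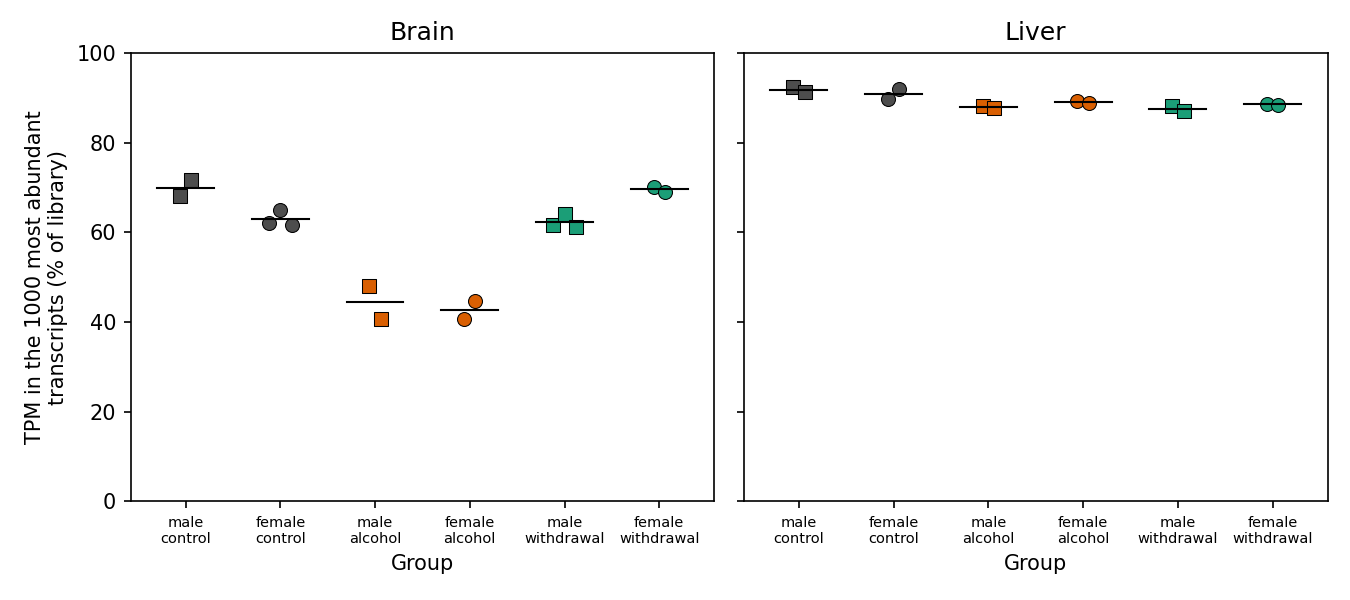
Share of TPM held by the 1000 most abundant transcripts of each library (y axis, percent of TPM) in each group of sex and exposure (x axis), for brain and liver; points are libraries and horizontal bars group means. Alcohol-exposed brains lie between 40.7% and 48.1%, below all control (61.5% to 71.6%) and withdrawal brains (61.3% and above).

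Over all 36682 tested brain transcripts, limma called 10281 higher and 9494 lower in alcohol-exposed than in control brains, averaged over sexes, and 1736 rose and 5663 fell by at least 2-fold. The transcript ENSDART00000163803.1 was listed at 0 in all 5 control brains and stood at 10.1 to 12.9 TPM in alcohol-exposed males and 11.1 to 12.0 TPM in alcohol-exposed females (limma adjusted p = 1.13e-07). ENSDART00000148406.1, also listed at 0 in the 5 control brains, reached 13.3 to 13.7 TPM in males and 7.75 to 10.8 TPM in females (adjusted p = 3.65e-10). ENSDART00000146351.1 fell from 442 to 709 TPM in control males and 253 to 457 TPM in control females to at most 24.4 TPM in males and a listed 0 in females (adjusted p = 5.71e-06). ENSDART00000154523.2 fell from 84.2 to 107 TPM in control females and 99.2 to 102 TPM in control males to at most 1.85 TPM under alcohol (adjusted p = 3.55e-09). The median of all transcripts shifted by 0.98 log2 units without rescaling, and the calls became 26708 higher and 3151 lower.

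Both sexes took part in the brain response. Males had 8462 higher and 8989 lower transcripts under alcohol, and females 6415 and 8148. The male and female log2 changes, which share no library, correlated across transcripts (Pearson r = 0.541, with transcripts not being independent replicates), and 8484 transcripts were called in the same direction in both sexes against 708 in opposite directions. Independent lists of these sizes would share 3477 and 3452. Quantile normalisation lowered r to 0.351. Without rescaling, the calls were 24168 higher and 2515 lower in males (median shift 1.11) and 23853 and 3208 in females (0.953), and with quantile normalisation 7638 and 5131 in females.

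In the liver, between 22.2% and 27.9% of transcripts rose under alcohol and between 19.6% and 36.0% fell in the classes up to 1000 TPM. Above 1000 TPM, the class with a mean of 72.0% of TPM in controls, 15 of 185 rose and 71 fell (median −0.44, which turned to 0.0042 without rescaling and 0.044 with quantile normalisation). Of 21158 tested transcripts, limma called 5102 higher and 4450 lower over both sexes, of which 1773 rose and 1038 fell by at least 2-fold. ENSDART00000169569.1 rose from 0.0956 to 0.207 TPM in control males to 531 to 1060 TPM in exposed males, and stood at 0 and 10.1 TPM in control females against 23.7 to 31.0 TPM in exposed females (log2 change 6.21, SE 0.69, limma adjusted p = 0.000265). ENSDART00000159742.1 was listed at 0 in control males and reached 562 to 661 TPM under alcohol, with 134 to 1110 TPM in control and 1120 to 1230 TPM in exposed females (adjusted p = 0.000182).

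Falling liver transcripts included ENSDART00000012842.8, at 1220 to 1660 TPM in control males and listed at 0 in all exposed livers (adjusted p = 0.00186), with 0 and 100 TPM in the female controls. ENSDART00000141225.2 stood at 238 to 328 TPM in control males, at 0 and 311 TPM in control females and was listed at 0 in all exposed livers (adjusted p = 0.00896). The call of the latter ended when nearly identical library pairs were averaged, which left fewer libraries in the fit (adjusted p = 0.0512, with a range from 1.53e-07 over its 19 alternatives). The 1000 most abundant transcripts held 88.5% ± 0.704 of TPM in exposed livers and 91.3% ± 1.19 in controls (SD, n = 4 each, exact two-sided permutation p = 0.0286, the smallest that 70 splits can give, and 0.0429 after adjustment).

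Male livers had 5458 higher and 4981 lower transcripts under alcohol, and female livers 1884 and 1480. Across transcripts the changes of males and females correlated with r = 0.164, and 1302 transcripts were called in the same direction and 531 in opposite directions, where independent lists would give 834 and 825. Without rescaling the liver calls became 7533 higher and 1646 lower over both sexes (median shift 0.24), 7404 and 2233 in males (0.335), and 2664 and 584 in females (0.158). The female count rested on few libraries, since it was 550 with nearly identical pairs averaged, 978 and 1141 without female alcohol replicates 2 and 1, and 1833 without female control replicate 1. The count over both sexes was 6273 with pairs averaged, the male count was 6712 when only male control and alcohol libraries were fitted, and r was 0.0723 without female control replicate 2.

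**Figure D3:**
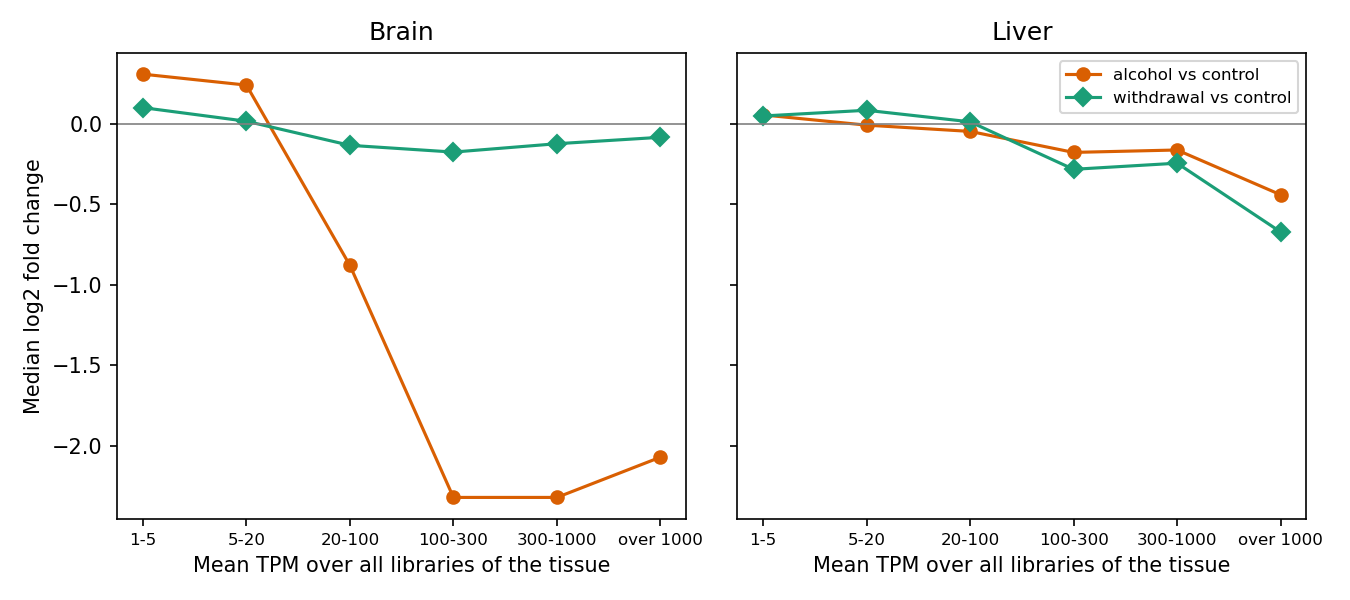
Median log2 change (y axis) of transcripts in classes of mean TPM over all libraries of a tissue (x axis), for alcohol against control and withdrawal against control over both sexes, in brain and liver. Brain classes above 100 TPM lie between −2.32 and −2.07 under alcohol and between −0.18 and −0.08 after withdrawal; signs depended on the scaling for the brain class of 20 to 100 TPM under alcohol (0.56 without rescaling), for that above 1000 TPM under quantile normalisation (0.00574), for those of 1 to 5 (−0.017) and 5 to 20 TPM (−0.027) after withdrawal under quantile normalisation, and for most liver classes.

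After withdrawal the TPM share of abundant brain transcripts lay below controls in males and above them in females, and the pooled means were close. The 1000 most abundant transcripts held 65.2% ± 4.14 (SD, n = 5) of TPM, against 65.7% ± 4.19 (SD, n = 5) in controls, with no difference by the pooled test (exact two-sided permutation p = 0.825). Within the sexes the shares did not overlap, at 61.3% to 64.1% in withdrawal against 68.1% to 71.6% in control males, and at 69.0% and above in withdrawal against 61.5% to 65.0% in control females. With 3 against 2 libraries these differences had an exact two-sided permutation p of 0.1 in each sex, the smallest that 10 splits can give, so neither could pass the test. From alcohol to withdrawal, 669 of 676 transcripts of 100 to 300 TPM rose, as did 257 of 258 at 300 to 1000 TPM and 81 of 81 above 1000 TPM. Without rescaling, the medians of these classes against control were −0.84, −0.82 and −0.56 under alcohol, and −0.10, −0.05 and −0.01 after withdrawal. With quantile normalisation they were −0.03, −0.00347 and 0.00574 under alcohol, and −0.08, −0.05 and −0.03 after withdrawal. The rise of these classes was seen with the rescaling and in the medians without it, but not under quantile normalisation. That method gives all libraries the same distribution, so it cannot show a shift of whole abundance classes. The TPM share of the 1000 most abundant transcripts needs no scaling between libraries. It was 43.5% in alcohol-exposed brains, below withdrawal brains (exact two-sided permutation p = 0.00794, adjusted 0.0238). For the exposed brains, exposure and preparation cannot be told apart. The transcript ENSDART00000146351.1, at most 24.4 TPM under alcohol, stood at 267 to 337 TPM in withdrawal males and at 255 to 621 TPM in withdrawal females. By contrast, ENSDART00000148406.1 remained at 9.52 to 10.1 TPM in withdrawal males and was listed at 0 in withdrawal females.

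Between withdrawal and control brains, limma called 4175 transcripts higher and 4077 lower over both sexes, with 853 and 353 past 2-fold. Between withdrawal and alcohol it called 9112 higher and 7835 lower. Without rescaling these were 3384 and 1657 against control, and 3180 and 26056 against alcohol (median shift −0.96), and quantile normalisation gave 5667 and 9305 against alcohol. The total of 8252 calls against control depended on single libraries, with 3846 without female withdrawal replicate 2 and 5202 without male control replicate 2, and was 4983 after quantile normalisation and 5041 without rescaling.

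The average over the sexes hid effects of opposite sign in the withdrawal brains. Males differed from their controls in 9074 higher and 9587 lower transcripts, and females in 5131 and 4343. Across transcripts the male and female differences correlated negatively (r = −0.524), and 6125 transcripts were called in opposite directions against 442 in the same direction, where independent lists would give 2415 and 2404. Transcripts above 1000 TPM had a median change of −0.81 in males and 0.40 in females. Without rescaling the calls were 12680 higher and 3509 lower in males (median shift 0.29), and 2296 and 9037 in females (−0.23).

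The female total of 9474 was 4347 when only female control and withdrawal libraries were fitted and 5654 without female withdrawal replicate 1. The negative r was −0.345 without that library.

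Withdrawal livers differed widely from control livers. Limma called 6939 transcripts higher and 6215 lower over both sexes, with 3003 and 2305 past 2-fold. The largest fall by the naming rule was a transcript at 3790 to 3830 TPM in control males and 21.8 to 35.7 TPM in control females that was listed at 0 in all withdrawal livers (limma adjusted p = 5.28e-08). Another transcript stood at 551 to 567 TPM in withdrawal females and 502 to 650 TPM in withdrawal males, against 56.2 to 58.5 TPM in control females and 0.215 to 0.359 TPM in control males (log2 change 6.03, SE 0.32, adjusted p = 3.45e-06). Under alcohol that transcript was at 0.351 to 0.424 TPM in females and 1.24 to 6.54 TPM in males (withdrawal against alcohol, log2 change 7.89, SE 0.32, adjusted p = 2.75e-06).

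The share of TPM in the 1000 most abundant liver transcripts was 88.0% ± 0.729 (SD, n = 4) after withdrawal, below the 91.3% ± 1.19 (SD, n = 4) of controls (exact two-sided permutation p = 0.0286, adjusted 0.0429), and did not pass the test against alcohol (p = 0.429, adjusted 0.515). Males had 7074 higher and 5939 lower transcripts against control, females 3605 and 3526, with r = 0.202 across transcripts and 3229 called in the same direction against 1162 in opposite directions (2195 and 2191 for independent lists). Between withdrawal and alcohol livers 4311 transcripts were higher and 4353 lower. Without rescaling the calls against control became 8882 higher and 3732 lower over both sexes (median shift 0.26), 8324 and 3867 in males (0.26), and 5311 and 2000 in females (0.22). With nearly identical pairs averaged, the withdrawal against alcohol total was 4029 and the female withdrawal total 2899, which was also 4380 and 4279 without female withdrawal replicates 1 and 2.

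Averaged over the sexes, a smaller share of the alcohol calls was still changed after withdrawal in the brain than in the liver, a difference that was not tested. Of the 19775 transcripts called under alcohol in the brain over both sexes, 50.8% returned, 28.9% were still changed, 2.59% were reversed and 17.7% were unresolved. Of the 9552 called in the liver, 14.5% returned, 72.7% were still changed, 4.32% were reversed and 8.41% were unresolved. The retained share of the alcohol effect was 0.217 ± 0.0624 in the brain and 0.996 ± 0.0233 in the liver (SD over 2 single withdrawal replicates, which share all control and alcohol libraries). The brain retained share lay below those of both sexes taken alone. The returned share of brain calls lay above those of both sexes taken alone, which were 19% in males and 44.3% in females. Withdrawal effects of opposite sign in the sexes cancel in the average, so a transcript can count as returned without having returned in either sex. In males alone the still changed shares lay closer, at 68.6% in the brain and 74.8% in the liver. The returned count of 10040 in the brain was 23805 without rescaling, and that of 1387 in the liver was 661 with pairs averaged and 917 without female alcohol replicate 2, where the still changed liver count of 6949 was 4619 with pairs averaged. The brain values start from exposed libraries in which exposure and preparation cannot be told apart. In male livers, the alcohol and withdrawal effects are both taken against the same 2 control libraries, which lay apart from all other livers. A preparation particular to those control libraries would enter both effects, and it cannot be told apart from exposure either. New calls after withdrawal that were absent under alcohol numbered 2017 in the brain and 5792 in the liver.

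The brain average covered unlike sexes. In males 68.6% of 17451 alcohol calls were still changed and 3323 returned, with a retained share of 0.631 ± 0.0137. Without rescaling 12197 were still changed and 11572 returned in males, nearly equal numbers, and 2028 returned without male alcohol replicate 1. In females 25.9% of 14563 were still changed and 44.3% returned, with a retained share of 0.298 ± 0.0306, and the returned count of 6454 was 16308 without rescaling. Male livers kept 74.8% of 10439 calls (retained share 1.03 ± 0.012) and female livers 55.3% of 3364 (0.699 ± 0.00845). The difference between the sexes in these shares was not tested. In female livers the still changed count of 1860 was 311 with pairs averaged, 659 and 733 without female alcohol replicates 2 and 1, 1005 without female control replicate 1, and 1228 and 1237 without female withdrawal replicates 1 and 2. The returned count of 934 was 121, 227, 266, and 619 in the first 4 of these settings and 610 without female withdrawal replicate 2. The returned count of 1488 in male livers was 868 without male alcohol replicate 2.

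**Figure D4:**
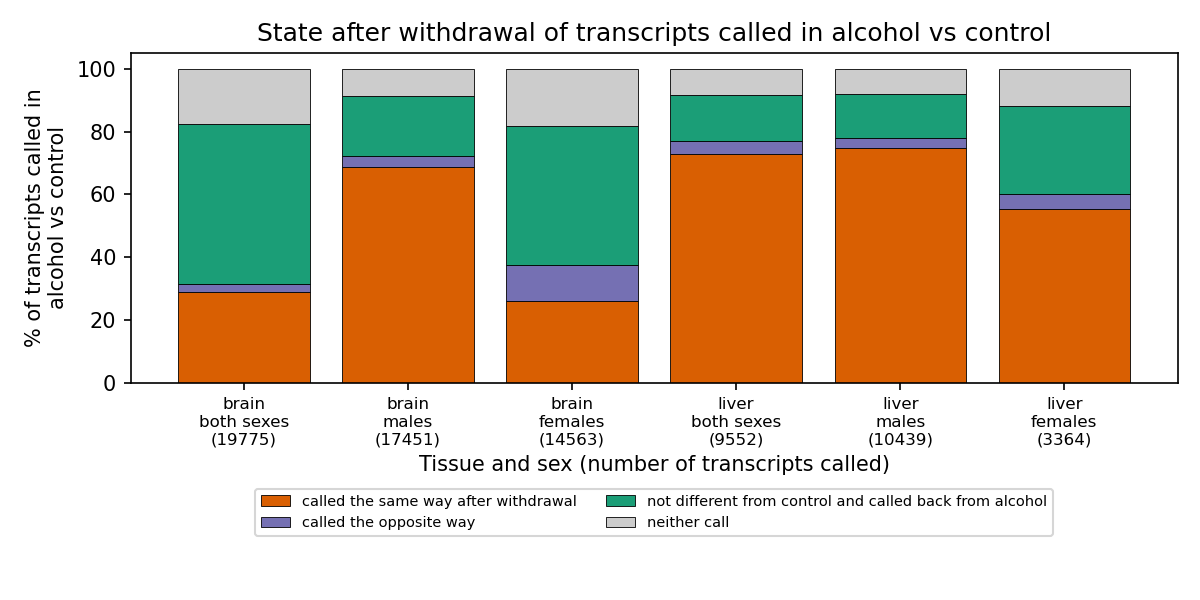
State after withdrawal of the transcripts called between alcohol and control (y axis, percent of the called transcripts), for each tissue and sex (x axis, with the number called); bar segments stand for still changed in the same direction, called in the opposite direction, returned, and unresolved. The still changed segment is 28.9% in brain and 72.7% in liver over both sexes.

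The alcohol and withdrawal effects share their control libraries. Unchanged groups simulated with the same design (20 simulations) gave r = 0.479 between the 2 effects in the brain, where 0.465 was observed. In the liver they gave 0.501, where 0.71 was observed. Shared calls had a mean of 0 in the brain and 0.05 in the liver. Without simulated changes hardly any transcript can be called, so these shared calls are no baseline for the still changed counts. The covariance was 0.206 in the brain against 0.0248 simulated (difference 0.181), and 0.55 in the liver against 0.0257 (difference 0.525). With the controls split so that the effects shared none, r was 0.379 on average in the brain (0.363 to 0.394) and 0.622 in the liver (0.613 to 0.632), with covariances of 0.184 and 0.509. Still changed transcripts numbered 5723 in the brain and 6949 in the liver. Independent lists would give 2225 and 2980, which makes no allowance for the shared controls. The still changed brain count over both sexes fell to 2783 without female withdrawal replicate 2, 3540 without male control replicate 2, 2763 with quantile normalisation and 3667 without rescaling.

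The difference between the sexes in the response to alcohol was tested in both tissues. In both tissues it includes the difference between control males and females, for which sex and library preparation cannot be told apart. In the brain 10086 transcripts passed the test of the difference itself, 5009 with a higher change in females and 5077 with a lower one. A transcript at 442 to 910 TPM in control females and listed at 0 in control males was listed at 0 in exposed females and stood at 1.46 and 137 TPM in exposed males, with 458 to 701 TPM in withdrawal males and a listed 0 in withdrawal females (limma adjusted p of the difference = 0.000821). In the liver 7337 transcripts passed, 3585 higher and 3752 lower. A liver transcript at 5940 to 6450 TPM in control males, listed at 0 in all female livers, fell to at most 0.639 TPM in exposed males and at most 0.117 TPM in withdrawal males (adjusted p of the difference = 2.25e-07).

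Without rescaling the brain differences were 2746 higher and 7683 lower (median shift −0.25) and the liver differences 2132 and 3918 (−0.163). The brain total was 6370 with pairs averaged, 6517 without female alcohol replicate 2 and 6625 without male control replicate 2, and the liver total 3703 with pairs averaged and 4807 without female alcohol replicate 1.

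Sexes differed in control brains in 13811 transcripts, 7029 higher and 6782 lower in females, and in control livers in 10977, 5804 higher and 5173 lower. The transcript with the largest female excess in control livers stood at 45500 to 64400 TPM in females and at most 0.0276 TPM in males (log2 difference 15.70, SE 0.19, limma adjusted p = 5.75e-10). Another transcript came so close (15.68, SE 0.73) that their order is not settled. In alcohol-exposed brains 2462 transcripts differed between the sexes, 1363 higher and 1099 lower in females, and in withdrawal brains 15510, 8128 higher and 7382 lower. Exposed livers had 3242 higher and 3020 lower in females, and withdrawal livers 4097 and 4527. Differences of the same sign in all 3 exposures were found for 377 female-high and 18 male-high transcripts in the brain (57.9 and 40.9 for independent lists), and for 544 and 536 in the liver (172 and 158).

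Without rescaling the female against male calls were 10189 and 2250 in control brains (median shift 0.23) and 3349 and 12413 in withdrawal brains (−0.30). The exposed brain total ran from 183, when only those 4 libraries were fitted, to 5103 with quantile normalisation, and the control brain total was 8818 without male control replicate 2.

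Across tissues the alcohol responses overlapped in part. Among 19361 transcripts tested in both tissues, 2016 rose and 2317 fell in both under alcohol, against 1229 and 1482 for independent lists, and 1546 moved in opposite directions, against 2755. The log2 changes correlated across transcripts with r = 0.278. After withdrawal, 1165 were higher and 1332 lower than control in both tissues, against 802 and 788, and 1036 moved in opposite directions, against 1592 (r = 0.247). The changes from alcohol to withdrawal were nearly unrelated between the tissues (r = 0.0116). These comparisons were made only with the rescaling, on which the alcohol calls of both tissues depended. For the exposed brains, exposure and preparation cannot be told apart.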

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

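The tests of exchanged sex labels, of transcripts listed at 0 and of a shared preparation were chosen after the result was seen. Effects of alcohol and of withdrawal that differed between males and females were called in both tissues, by a limma test of the difference itself. For alcohol the difference passed for 10086 brain transcripts (5009 with a higher change in females, 5077 with a lower one) and for 7337 liver transcripts (3585 and 3752). For withdrawal it passed for 19393 brain transcripts (10083 and 9310) and for 10671 liver transcripts (4813 and 5858). Without rescaling the differences were 3896 higher and 14604 lower for brain withdrawal (median shift −0.53), 2746 and 7683 for brain alcohol (−0.25), and 2132 and 3918 for liver alcohol (−0.163). In both tissues these differences include that between control males and females, for which sex and library preparation cannot be told apart. No group held enough libraries for a test of single outlying libraries.

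In the brain, sex differences of controls and of withdrawal fish ran in opposite directions: 8195 transcripts were called between the sexes in opposite directions and 799 in the same direction (2917 and 2922 for independent lists; r = −0.385 across transcripts, with no library shared). An exchange of sex labels in either group was argued against, since of 162 transcripts sex-biased in the same direction in alcohol-exposed brains and in all liver exposures, 85.8% kept that direction in control and 83.3% in withdrawal brains. That test covers sex labels alone. Control and withdrawal labels exchanged within a sex would leave these directions as they are, so it cannot speak to such an exchange. Transcripts that switch to a listed 0 were argued against as the whole cause. The male and female withdrawal effects correlated at −0.572 over the 27390 transcripts above 0 in every brain library, against −0.524 over all. Reads moved between similar transcripts that stay above 0 are not removed by this test, so that explanation stays open. A preparation batch shared by control males with withdrawal females, and by control females with withdrawal males, cannot be told apart from an effect of sex on withdrawal: the labels give no batch, and control male libraries correlated at 0.91 with withdrawal females, above 0.893 with control females and 0.861 with withdrawal males, and control females at 0.934 with withdrawal males. An effect of withdrawal that depends on sex stays open and was not tested apart from a shared batch or from exchanged exposure labels.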

How the results depend on the processing

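Averaging of nearly identical pairs (female alcohol brain, female alcohol liver, female withdrawal liver) and quantile normalisation were chosen after seeing the data. Male withdrawal brain, whose replicates 1 and 2 differed by 0.0992, was not averaged, so that group was not put to this check. No named transcript changed its direction under these alternatives, but some medians of abundance classes turned sign with the scaling (brain, 20 to 100 TPM under alcohol: −0.88, and 0.56 without rescaling). Of the recomputed counts of called transcripts 438 stayed within 1.5 times, 36 were lower and 6 higher; of the recomputed single transcript results 794 held and 2 lost their call: a brain withdrawal rise without male control 2 (limma adjusted p = 0.0529, range from 4.92e-05) and a liver alcohol fall with pairs averaged (0.0512, range from 1.53e-07), each listed at 0 in every library of a compared group and with fewer libraries fitted. Correlations between the sexes held in 75 cases and moved in 5. Counts of transcripts by state after withdrawal held in 205 cases, with 20 lower and 3 higher. Neither the pseudocount nor the filter moved a count of calls by over 1.5 times. Set tests of gene lists were not run, since no map from transcript to gene was used here.

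Without rescaling, brain calls were 29859 for alcohol, 5041 for withdrawal, 29236 for withdrawal against alcohol, 26683 for male and 27061 for female alcohol, and 4406 between exposed sexes; the cause was not tested. Quantile normalisation gave 4983 for brain withdrawal and 5103 between exposed sexes. Fitting only the compared groups, which leaves fewer libraries to estimate the spread, gave 4347 for female brain withdrawal, 183 between exposed brain sexes, 6712 for male liver alcohol and 3989 between exposed liver sexes. Averaging pairs, which leaves fewer libraries, gave 6370 for the sex difference of the brain alcohol effect and 778 between exposed brain sexes, and in the liver 6273 for alcohol, 4029 for withdrawal against alcohol, 550 and 2899 for female alcohol and withdrawal, 3703 for the sex difference of alcohol, and 2364 and 4137 between exposed and withdrawal sexes. The liver retained share was 0.965 without rescaling, 1.04 with the smaller pseudocount and 0.952 with quantile normalisation; the cause was not tested, and the averaged and block settings gave no such share.

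Leaving out single libraries, brain counts ran from 3846 (without female withdrawal 2; 5202 without male control 2) to 10130 for withdrawal, 5654 (female withdrawal 1) to 9921 for female withdrawal, 6517 (female alcohol 2; 6625 without male control 2) to 10892 for the sex difference of alcohol, and between sexes 8818 (male control 2) to 14278 in controls, 765 (female alcohol 2; 1028 and 1148 without female alcohol 1 and male alcohol 2) to 2683 under alcohol, and 9712 (female withdrawal 1) to 15825 after withdrawal. Liver counts ran from 978 (female alcohol 2; 1141 and 1833 without female alcohol 1 and female control 1) to 4082 for female alcohol, 4279 (female withdrawal 2; 4380 without 1) to 7796 for female withdrawal, 4807 (female alcohol 1) to 7383 for the sex difference of alcohol, and between sexes 3283 (female alcohol 2; 3350 without 1) to 6358 under alcohol and 4859 (male withdrawal 1; 5525 without female withdrawal 2) to 9295 after withdrawal. Where this left a group with 1 library, that library was assumed to vary like the other groups.

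Replicate numbers did not pair the libraries: deviations from group means correlated at −0.0271 on average between same-numbered brain libraries (31 pairs, −0.179 to 0.0638) and at 0.0097 in liver (30 pairs, −0.0369 to 0.101). The replicate block gave 1565 calls between exposed brain sexes and moved no other count of calls by over 1.5 times. Depth is unknown, so its effect on transcripts of low abundance could not be assessed.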

Other observations

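The tests of an even background, of the 20 most abundant transcripts, of library preparation and of carried-over female RNA were chosen after the result was seen, as were the counts of transcripts that switch between 0 and at least 20 TPM. In male livers, 99 transcripts were listed at 0 in both control libraries and stood at 20 TPM or more in both withdrawal libraries, and 34 did the reverse, although control female and control male livers also differed by 133 such transcripts. Between control and alcohol-exposed male livers 31 appeared and 24 disappeared in this sense, and between control and withdrawal female livers 9 appeared and 10 disappeared. Single replicate pairs within a liver group gave 1 to 23, by a more lenient comparison of 2 libraries.

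The abundance profile of all 4 alcohol-exposed brain libraries was flatter than that of any other brain library, by 13.2 percentage points between 48.1% and 61.3% in the TPM share of the 1000 most abundant transcripts. An even background of reads over all transcripts was argued against, because the median gain in TPM of transcripts of 5 to 20 TPM was 3.5 times that of transcripts of 1 to 5 TPM in males and 3.54 times in females, with classes set by the withdrawal brains, which do not enter the gain, and where an even gain would be equal. The 20 most abundant transcripts alone were argued against as the cause, since 0.961 of the log2 rise of transcripts of 1 to 20 TPM stayed in males and 0.97 in females after they were removed. A preparation particular to the exposed brain group cannot be told apart from ethanol, since all 4 exposed libraries share group and exposure and no control or withdrawal library had the same profile. An effect of ethanol on the abundance profile therefore stays open, as a hypothesis that these libraries do not separate from preparation.

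In the liver, 8 transcripts stood at 1000 TPM or more in every female library and under 10 TPM in control males. Their withdrawal female means ran from 4110 to 113000 TPM. All 8 were higher in male withdrawal than in male control livers, at a median of 1.1 TPM. Picking transcripts that are low in control males favours such a rise. In exposed males ENSDART00000078225.6 stood higher than in withdrawal males (18 against 4.72 TPM), and the others stood lower. Carry-over of female liver RNA or reads would put all 8 at the same ratio to the female level. The top and bottom deciles of these ratios differed 17.1 times. In all 12 pairs of a male withdrawal with a female library they differed over 10 times (11.2 to 71.5). The 4 transcripts at 1 TPM or more in withdrawal males lay closer, at 0.0106% to 0.032% of the female level, and the spread comes from transcripts under 1 TPM there; the one with the lowest ratio stood at 22100 TPM in withdrawal females and at 0.0584 and 0.16 TPM in withdrawal males, where the ratio of the most abundant transcript would put it at 3.92 TPM. The spread exceeded a bound of 10 times that was written after the pattern was seen. It rests on transcripts under 1 TPM, for which no detection floor is known, so it does not decide on carry-over at a single ratio. Carry-over, the allocation of reads between similar transcripts and low expression in withdrawal males stay open and were not tested apart.

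Whether other splits of the same libraries gave as many calls was counted with a model of split and sex on the compared libraries alone, so that its counts differ from those of the report. The split of males against females cannot be fitted beside sex and was left out of these counts after its result was seen. Without a term for sex it called 2622, 671 and 1569 transcripts in the liver comparisons below, in their order. In the brain it called 281 for alcohol against control, 1583 for withdrawal against alcohol and 122 for withdrawal against control. For brain alcohol against control the real split called 13992 transcripts and the highest other 5608, and 1 of 99 splits, the real one, reached that number. For brain withdrawal against alcohol the numbers were 12104 and 1575, with 1 of 100. Both shares lie under 0.05 when single libraries are exchanged. Replicate libraries are pools that may be technical, so these splits cannot exclude chance differences between pools or tanks. For brain withdrawal against control the real split called 40 and the highest other 9539. As many were called by 3 of 99 splits, or by 4 of 100 with the split by sex. These shares also lie under 0.05, but they concern 40 calls and leave chance open for the 8252 calls of the 6-group model. The split with 9539 calls set control males, withdrawal females and female control 2 against withdrawal males and the other control females, which points to a structure of the samples. In the liver 1 of 34 splits, the real one, called as many for alcohol against control (2052, highest other 46), for withdrawal against control (5218, highest other 218) and for withdrawal against alcohol (2907, highest other 531), a share of 2.94%. For the withdrawal comparisons the share stayed under 0.05 with the split by sex (2.86%). For liver alcohol against control it did not, since the split by sex called more than the real one. With it, 2 of 35 splits called as many (5.71%). As in the brain, libraries that may be technical are exchanged here. Chance differences between pools or tanks are therefore not excluded for any liver comparison.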
